A study of Mus musculus with 6 samples.

How the data were processed

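RNA-seq was done on cells sorted as cKit-positive and lineage-negative from the bone marrow of 6 mice of the C57BL/6 strain, 3 controls that carry the Mx1-Cre transgene and 3 mice that carry it together with floxed Cdc73 alleles. Cre under the Mx1 promoter is switched on by interferon, here through an injection of 50 µg of polyinosinic:polycytidylic acid, abbreviated poly(I:C), and both groups received it 2 days before harvest. Per the labels' protocols, cells came from 2 tibias and 2 femurs, and cells with surface antigens of mature T, B, NK, dendritic, myeloid or red cells were left out of the sort. The labels also state that total RNA was depleted of ribosomal RNA and that the library kit was made for low input. The design text counts 3 mice per group, so each library was taken as 1 mouse. Whether the counting used strand is not given in the sources used here.

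The authors deposited a table of normalized signal per gene for the 6 libraries and a table of their own comparison. Per the submitters' processing notes, bcl2fastq 2.17, STAR, HTSeq and DESeq2 were used with the mouse genome build GRCm38.p5, and the notes give no settings. The deposited signal values are gene counts divided by 1 size factor per library: in each library 100% of the values above 0 were whole multiples of what 1 read is worth, within 0.01 of a whole read. Multiplying back gave 16801647, 23367842 and 21766447 reads in genes in the 3 controls and 18625158, 26440706 and 19617415 in the 3 Cdc73-deleted libraries, so that 1 read was worth between 0.796 and 1.19 normalized counts. The table held 26976 rows, of which 1 repeated an identifier and was left out. The 1065 rows without a symbol took one from the reference table where it had one, which was the case for 1064. The authors' deposited table of the comparison gives a log2 fold change and an adjusted p-value per gene and has no values per library.

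Since the deposited values are normalized and not raw counts, the main test was limma 3.58.1 with a mean-variance trend on log2(normalized count + 1), over genes with a normalized count of at least 10 in at least 3 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan made before the data were examined was an edgeR quasi-likelihood test on raw counts with TMM scaling and edgeR's own filter on low counts. As an added alternative, edgeR 4.0.16 with TMM scaling was run on the recovered reads of the genes that passed the limma filter, and called 6657 genes. The planned filter was not used. Fold changes are differences of group means on the log2(normalized count + 1) scale. The added 1 tends to shrink the change of genes with low counts. Means of logs can also give a larger change than the ratio of the mean counts, as for Cyp11a1, at 4.21 here and 3.89 in the authors' deposited table. Errors given with fold changes are the moderated standard errors of limma. Levels are means of normalized counts with the SD over 3 libraries. R 4.3.3 was used, and figures were drawn with matplotlib 3.10.9.

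The 30 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests a list without reference to other genes, were alternatives. The named genes followed a rule set before the data were examined. They are Cdc73, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold with at least 5 CPM (reads of the gene scaled by the total of the library) in the higher group, no overlap between the groups and a symbol that is not a predicted, clone-based or pseudogene name, and from each list the 4 members past the threshold with the smallest adjusted p, or 2 members given as values where none passed. Other genes that are named make up a small count in a list or were singled out, and were chosen after their values were seen.

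Shares of reads were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1. Gene positions, gene classes and exon overlaps came from GENCODE release M21 on GRCm38, matched by identifier without version for 99.8% of the rows. No 2 libraries of a group held the same values: chi-square per degree of freedom between pairs of one group lay between 9.43 and 15.0, far above sampling noise, so each library counted as 1 replicate.

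Alternatives covered other scalings (TMM, DESeq2 size factors, total counts), filters, pseudocounts of 0.5 and 5, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, lists without members of other lists, and a null hypothesis of a change up to 1.5-fold. The test was tried on simulated counts for the comparison of Cdc73-deleted and control libraries, drawn for 13887 genes from the real means, dispersions and library sizes. It recovered 89.4% of the 66 genes changed 4-fold, 65.7% of the 67 changed 2-fold and 47.8% of the 67 changed 1.5-fold. In that simulation 10 of 145 calls were false, and 2 genes were called in a simulation without any change. The simulation changed only a small share of the genes, while 48.3% of the tested genes were called in the data. The adjusted threshold depends on that share, so these rates do not give the sensitivity of the real comparison. Sex as a covariate was not used, because all 6 libraries held at least 10013 reads of Xist and at most 1 read of any Y-linked gene in the lists.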

Results

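Transcripts were measured by RNA-seq in cKit-positive, lineage-negative bone marrow cells, a sort that holds haematopoietic stem and progenitor cells, from 3 control mice and 3 mice in which Cdc73 had been deleted with Mx1-Cre. Cdc73 is a subunit of the PAF1 complex, which travels with RNA polymerase II during elongation. The comparison asks which genes depend on Cdc73 in these cells 2 days after poly(I:C), which both groups received. Reads in genes ranged from 16801647 to 23367842 in the controls and from 18625158 to 26440706 in the Cdc73-deleted libraries, and 13887 of the 26975 genes passed the filter on low counts. Levels are normalized counts as mean ± SD (n = 3 libraries per group), and changes are log2 fold changes of Cdc73-deleted over control cells ± SE with the adjusted p of limma. Members named because few of a list moved their way were chosen after their values were seen.

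Cdc73 itself (ENSMUSG00000026361, chromosome 1 from 143598800 to 143702893 on GRCm38) was lower in all 3 libraries of mice with the floxed alleles. Its level was 1742 ± 34.7 in control and 675 ± 69.1 in Cdc73-deleted cells, a change of −1.37 ± 0.09 (adjusted p = 3.41e-07), or 2.59-fold lower. The value sums all exons of the gene, so reads from exons outside the deleted part still count, and it does not give the share of cells with the deletion. Of the other 5 tested subunits of the PAF1 complex, 3 rose, namely Paf1 (0.60 ± 0.07), Ctr9 (0.27 ± 0.07) and Leo1 (0.31 ± 0.08), while Rtf1 and Wdr61 had values of 0.12 and 0.10 that did not pass the test (camera adjusted p = 0.0376, and adjusted p = 0.429 with an estimated correlation). The list's call ended without control replicate 1 (camera adjusted p = 0.0550), control replicate 2 (0.0546), Cdc73-deleted replicate 1 (0.0528) or Cdc73-deleted replicate 3 (0.0636), and Ctr9 was not called without Cdc73-deleted replicate 1 (adjusted p = 0.0510).

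Many granulocyte and monocyte genes fell in Cdc73-deleted cells, such as Elane and F13a1, and many immediate early, histone and stem cell genes rose. In total 6707 genes changed, 48.3% of those tested, with 3206 higher and 3501 lower in Cdc73-deleted cells, and 7648 had an unadjusted p under 0.05. Counts of list members are to be read beside these shares of all genes, and a count near them is no result about its list. A change of at least 2-fold was found for 1034 higher and 813 lower genes, 1847 in all, and for 700 of the 9505 genes with a mean of at least 5 CPM. The groups did not overlap for 57.3% of the tested genes, against 10% expected by chance. On a principal component analysis the first component, with 63.8% of the variance, separated the groups, and the second, with 16.6%, set control replicate 3 apart from the other controls.

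**Figure D1:**
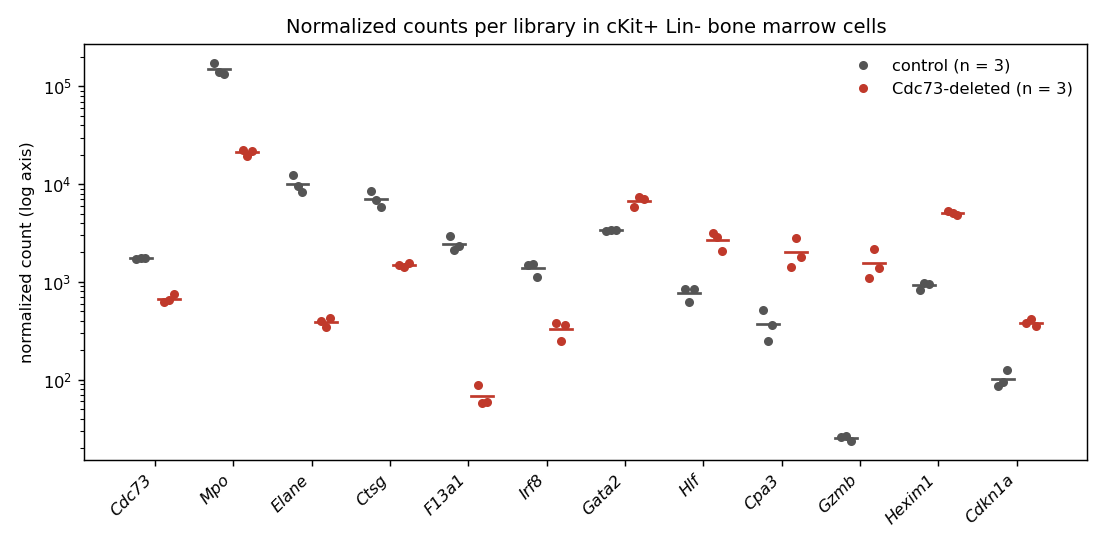
Normalized counts (log axis) of 12 named genes in each library, with a line at the mean of each group of 3 libraries. The libraries of the groups do not overlap for any of these genes, and Elane falls from a mean of 10138 to 389 while Gzmb rises from 25.4 to 1554.

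Among the genes the naming rule admits, the largest fall was that of Mefv, which encodes pyrin, from 163 ± 54.9 to 2.24 ± 1.05 normalized counts (ENSMUSG00000022534, chromosome 16 from 3707218 to 3718097, −5.66 ± 0.45, adjusted p = 1.74e-06). F13a1, the A chain of coagulation factor XIII found in monocytes, fell from 2459 ± 409 to 68.1 ± 16.8 (ENSMUSG00000039109, chromosome 13 from 36867178 to 37050244, −5.17 ± 0.17). Elane, the neutrophil elastase of primary granules, fell from 10138 ± 2199 to 389 ± 43.5 (ENSMUSG00000020125, chromosome 10 from 79886247 to 79888215, −4.69 ± 0.13). The other large falls were Nrp1 (−5.13 ± 0.66), Prom1 (−4.60 ± 0.48), Ly6c2 (−4.56 ± 0.42), Ifi209 (−4.15 ± 0.24) and Ly86 (−4.11 ± 0.38). Ly6c2 and Ifi209 belong to families of similar neighbouring genes, among which reads may be divided. The largest rise was that of Cma1, the mast cell chymase, from 3.05 ± 2.65 to 545 ± 323 (ENSMUSG00000022225, chromosome 14 from 55941451 to 55944675, 7.29 ± 0.60, adjusted p = 2.16e-06). Gzmb, the cytotoxic protease granzyme B, rose from 25.4 ± 1.49 to 1554 ± 559 (ENSMUSG00000015437, chromosome 14 from 56258838 to 56262260, 5.82 ± 0.22), and Id2, an inhibitor of basic helix-loop-helix transcription factors, from 21.5 ± 7.04 to 358 ± 114 (ENSMUSG00000020644, chromosome 12 from 25093799 to 25097140, adjusted p = 7.92e-07). The other large rises were Olfm5 (4.50 ± 0.47), Cyp11a1, an enzyme of steroid synthesis (4.21 ± 0.60), Nup210l (3.92 ± 0.31), the cell cycle inhibitor Cdkn1c (3.48 ± 0.32) and the prostaglandin synthase Ptgs2 (3.44 ± 0.32). In Cdkn1c 30.7% of the exon bases lie in exons of another annotated gene, so its reads are less certain.

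The list of neutrophils and their granules held 24 genes, of which those below the filter had at most 20.3 normalized counts in any library. Of the 14 tested genes, 11 fell and 1 rose (camera adjusted p = 6.83e-06, and adjusted p = 0.399 with an estimated correlation). Besides Elane these included the myeloperoxidase gene Mpo, from 149623 ± 21628 to 21153 ± 1457 (−2.81 ± 0.10), Ms4a3 (−2.83 ± 0.12) and cathepsin G, Ctsg (−2.22 ± 0.11), and the gene that rose was Padi4 (0.82 ± 0.17). Of 22 genes of monocytes, macrophages and dendritic cells, 10 fell and 3 rose (camera adjusted p = 0.00614, and adjusted p = 0.399 with an estimated correlation). The falls were led by F13a1, the chemokine receptor Ccr2 (−3.43 ± 0.17), Ms4a6c (−2.61 ± 0.17) and the transcription factor Irf8 (−2.07 ± 0.16), and the genes that rose were Cd74 (2.10 ± 0.40), Klf4 (1.39 ± 0.39) and Lyz2 (0.43 ± 0.14). In Ms4a6c 53.1% of the exon bases overlap another gene, and in Mpo 15%. The list of B cells and lymphoid progenitors held 24 genes, of which 21 were in the table and 7 passed the filter. Among those below it, Cd19, Cd79a and Pax5 had at most 4.49 normalized counts in any library, while Igkc and Jchain reached 896 and 229. Of the 7 tested genes, 4 fell and none rose (camera adjusted p = 0.0267, and adjusted p = 0.399 with an estimated correlation). They were Dntt, which adds nucleotides to rearranging receptor genes, from 551 ± 205 to 61.5 ± 21.4 (−3.13 ± 0.28), Ighm (−2.37 ± 0.21), Cecr2 (−1.10 ± 0.23) and Rag2, which had a mean of 19.1 ± 3.85 in control and at most 1.12 normalized counts in any Cdc73-deleted library. This list's call ended without control replicate 1 (camera adjusted p = 0.0550).

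Many red cell genes also fell. Of 24 tested erythroid genes, 17 fell and 2 rose (18 and 2 when adjusted over the list alone), with a median of −0.91 (camera adjusted p = 0.000398, and adjusted p = 0.429 with an estimated correlation). The membrane skeleton gene Sptb changed by −1.97 ± 0.25, Rhd by −1.92 ± 0.25 and Rhag by −1.76 ± 0.21, while Nfe2 (0.82 ± 0.07) and Hbb-bt (2.23 ± 0.38) rose. Of 14 genes of haem synthesis and iron uptake, 11 fell and none rose (camera adjusted p = 6.41e-05, and adjusted p = 0.399 with an estimated correlation), among them the haem synthesis enzymes Hmbs (−1.25 ± 0.11), Cpox (−1.10 ± 0.13), Alad (−1.03 ± 0.13) and Urod (−0.73 ± 0.09). The mean change of the erythroid list was −1.03, −0.63 and −0.32 in the 3 Cdc73-deleted libraries. Haemoglobin reads were rare, at 0.000188% of reads in control and 0.000636% in Cdc73-deleted libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow).

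Of 27 tested haematopoietic stem cell genes, 16 rose and 2, Ifitm1 and Erg, fell (camera adjusted p = 0.000403, and adjusted p = 0.399 with an estimated correlation). The falls were 0 without Cdc73-deleted replicate 2, 1 without control replicate 1, control replicate 2 or Cdc73-deleted replicate 3, and 3 without control replicate 3. The transcription factor Hlf rose from 768 ± 130 to 2704 ± 557 (1.81 ± 0.15), Mycn from 318 ± 27.6 to 1375 ± 224 (2.10 ± 0.13), Gata2 from 3364 ± 57.9 to 6703 ± 776 (0.99 ± 0.08) and the surface antigen Cd34 from 4909 ± 308 to 9054 ± 1198 (0.88 ± 0.09). Of 20 Hox, Meis and other targets of the MLL methyltransferase, 8 rose and 2, Cdk6 and Myb, fell (camera adjusted p = 0.0252, and adjusted p = 0.429 with an estimated correlation). Meis1 changed by 1.07 ± 0.09, Hoxa9 by 0.94 ± 0.11, Hoxa7 by 0.86 ± 0.12 and Hoxa10 by 1.98 ± 0.34, with 18.3% of the exon bases of Meis1 and 20.4% of those of Hoxa7 in exons of another gene. This list lost its call without control replicate 2 (camera adjusted p = 0.0568). Of 22 megakaryocyte and platelet genes 7 rose and 2, Gfi1b and Pf4, fell, and the list was not called (camera adjusted p = 0.119) except without Cdc73-deleted replicate 1 (camera adjusted p = 0.0412). Adjusted over the list alone, 7 rose and 1 fell. The falls were 0 without control replicate 1, control replicate 3 or Cdc73-deleted replicate 1, and 0 with DESeq2. Its leading members were the thrombin receptor F2r (0.89 ± 0.10), the thrombopoietin receptor Mpl (1.09 ± 0.14), Nbeal2 (0.81 ± 0.11) and Rab27b (0.81 ± 0.14).

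Mast cells also carry cKit, and several of their genes rose, while the tested members of a list of lymphoid effector cells moved both ways. Of 16 tested genes of mast cells, basophils and eosinophils, 8 rose and 2 fell (9 and 2 when adjusted over the list alone), with a median of 0.50 (camera adjusted p = 0.0234, and adjusted p = 0.399 with an estimated correlation). Besides Cma1 and Gata2, the mast cell protease Cpa3 rose from 374 ± 132 to 2012 ± 704 (2.43 ± 0.24), while the histidine decarboxylase gene Hdc (−0.93 ± 0.10) and Ifitm1 (−0.49 ± 0.16) fell. Tpsb2 had no reads in any control and a mean of 41.4 ± 20.1 in Cdc73-deleted cells, at least 13.8-fold higher against a floor of 3 counts per library, and the list's median was 0.50 with this gene at its bound. Over the alternatives the median lay between 0.26, without control replicate 2, and 0.69, without control replicate 1, and it was 0.33 in edgeR with TMM. The list lost its call without control replicate 2 (camera adjusted p = 0.0568), and 1 member fell without Cdc73-deleted replicate 2. Of the 25 genes in the list of T, NK and innate lymphoid cells, 21 were in the table and 9 passed the filter. The others in the table had at most 24.7 normalized counts in any library, and the sort left out mature T and NK cells. Of the 9 tested genes, Gzmb, Id2, Gata3 (1.13 ± 0.28) and Rora (0.94 ± 0.32) rose, and Nkg7 (−1.45 ± 0.12) and Tcf7 (−2.40 ± 0.58) fell. This list was not called (camera adjusted p = 0.143). Gzmb and Id2 were highest in Cdc73-deleted replicate 2 (2175 and 490 normalized counts), as were Cma1 (917) and Cpa3 (2795). Which cells held Gzmb was not tested. Of 8 stromal, endothelial and adipose genes, Pecam1 (−0.58 ± 0.10), Vcam1 (−1.97 ± 0.45) and Tie1 (−0.55 ± 0.15) fell, and the list was not called (camera adjusted p = 0.148). The sex-linked transcripts Xist and Tsix had values of −0.12 ± 0.06 and 0.25 ± 0.47 and did not pass the test (camera adjusted p = 0.762, with a camera direction below 0 and a median of 0.07, which was −0.08 without control replicate 2 and 0.24 without control replicate 1). The 2 genes overlap, with 32.6% of the exon bases of Tsix and 12.6% of those of Xist in exons of another gene, so Tsix may hold reads of Xist.

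**Figure D2:**
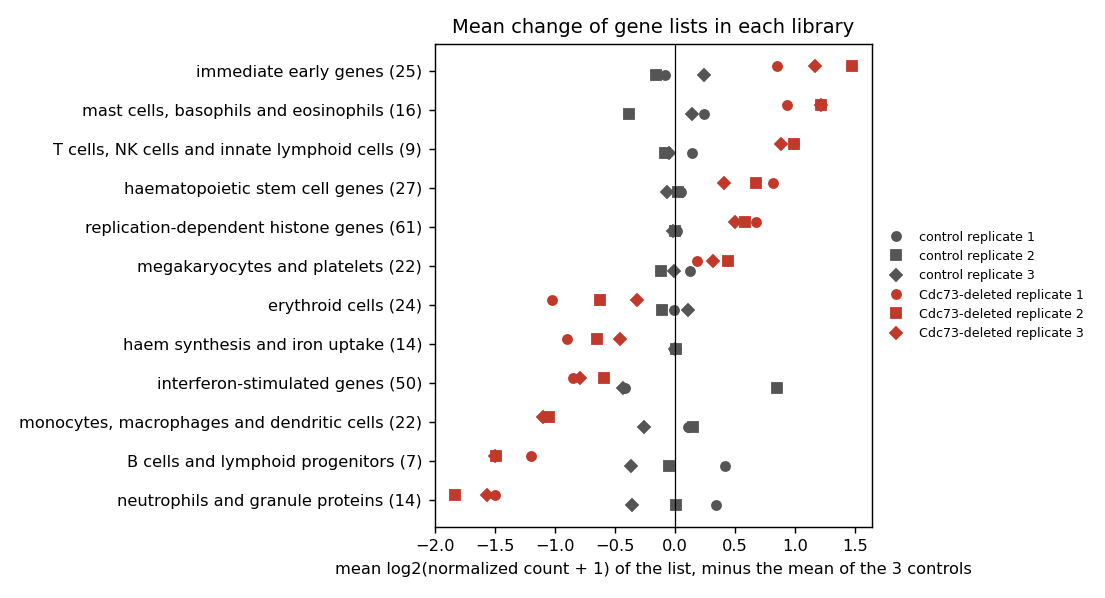
Mean of log2(normalized count + 1) over the tested members of 12 gene lists in each library, minus the mean of the 3 controls; the number of tested members stands in brackets. The neutrophil list lies between −1.50 and −1.84 in the Cdc73-deleted libraries, and control replicate 2 lies at 0.85 for the interferon-stimulated genes, above the other controls.

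Many genes of early stimulation and inflammation rose, and 24 of 50 interferon-stimulated genes fell. Of 25 immediate early genes, 20 rose and 1, Hspa1a, fell (camera adjusted p = 7.18e-09, and adjusted p = 0.399 with an estimated correlation). The falls were 0 without control replicate 1, control replicate 2 or Cdc73-deleted replicate 1. Ier5 rose from 487 ± 85.9 to 1975 ± 162 (2.03 ± 0.12), the nuclear receptor Nr4a2 by 2.33 ± 0.18, Zfp36, which promotes decay of AU-rich messenger RNA, by 1.58 ± 0.13 and Junb by 1.44 ± 0.10. Of 22 NF-kB and inflammatory genes, 13 rose and 2, Ikbke and Tnfaip2, fell (13 and 3 when adjusted over the list alone, camera adjusted p = 0.00626, and adjusted p = 0.399 with an estimated correlation). Tnf rose from 34.6 ± 7.35 to 265 ± 26.3 (2.92 ± 0.22), the inhibitor Nfkbia by 1.25 ± 0.09 and Nfkbiz by 1.33 ± 0.16, beside Ptgs2. Of 50 interferon-stimulated genes, 24 fell and 1, Cxcl10, rose (camera adjusted p = 1.91e-05, and adjusted p = 0.469 with an estimated correlation). The remaining 25 did not pass the test, and the list was not called by fry (adjusted p = 0.112). Ifit2 changed by −1.14 ± 0.11, Isg20 by −1.42 ± 0.21, Oasl1 by −1.41 ± 0.22 and Trim30a by −0.90 ± 0.15. The controls differed in this list, with mean deviations of −0.42, 0.85 and −0.44 from their common mean, and the Cdc73-deleted libraries lay at −0.85, −0.59 and −0.79. Without control replicate 2, 17 members fell and 4 rose, with a median of −0.36 in place of −0.68, and without Cdc73-deleted replicate 1, 15 fell. None rose without control replicate 1 or without any 1 of the Cdc73-deleted libraries.

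Some genes of growth arrest and survival rose and others fell. Among all 13887 tested genes 3206 rose and 3501 fell, so counts of members near these shares say little about a list. Of 36 p53 target genes 15 rose and 6 fell, and the list was not called (camera adjusted p = 0.0730). Cdkn1a, the inhibitor p21, rose from 102 ± 20.2 to 383 ± 33.4 (1.92 ± 0.17), Plk2 by 2.48 ± 0.25, Pmaip1 by 1.23 ± 0.17, and Gadd45a went from 444 ± 49.6 to 883 ± 31.8 normalized counts. Of 6 cyclin-dependent kinase inhibitors, Cdkn1a, Cdkn1c, Cdkn2d (0.96 ± 0.15) and Cdkn1b (0.44 ± 0.09) rose and Cdkn3 (−0.90 ± 0.20) fell (camera adjusted p = 0.0206, and adjusted p = 0.399 with an estimated correlation). The call of the kinase inhibitor list ended without members of other lists (camera adjusted p = 0.0726). Of 13 genes of the Bcl2 family, the survival genes Bcl2l1 (1.14 ± 0.12) and Mcl1 (0.57 ± 0.06) and the death-promoting Pmaip1 and Bok (1.46 ± 0.47) rose, and Bid (−0.69 ± 0.09) and Bak1 (−0.38 ± 0.14) fell, and the list was not called (camera adjusted p = 0.138). Of its falls 1 was left without control replicate 2 or any 1 of the Cdc73-deleted libraries, and with DESeq2. Of 52 DNA replication and S phase genes 9 rose and 18 fell. Mcm6 was at −0.60 ± 0.06, Pold1 at −0.68 ± 0.07, Prim1 at −0.70 ± 0.09 and Pcna at 0.70 ± 0.08, and the list was not called (camera adjusted p = 0.206). Of 53 G2/M and mitosis genes 22 rose and 10 fell (23 and 10 when adjusted over the list alone, camera adjusted p = 0.0252, and adjusted p = 0.550 with an estimated correlation), and the list was not called by fry (adjusted p = 0.0633). Kif20a, of whose exon bases 29.3% lie in another gene, was at 0.93 ± 0.07, Cdc20 at 0.73 ± 0.09, Gtse1 at 0.67 ± 0.10 and Ccnb2 at −0.60 ± 0.09. The mitosis list lost its call without control replicate 1 (camera adjusted p = 0.0883) and without Cdc73-deleted replicate 3 (camera adjusted p = 0.0623).

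Among the histone-modifying and elongation partners of the PAF1 complex, Hexim1, which holds the elongation kinase P-TEFb inactive, rose from 920 ± 85.4 to 5068 ± 210 (2.46 ± 0.08, adjusted p = 1.08e-09). The P-TEFb subunits Cdk9 (0.82 ± 0.09), Ccnt2 (0.74 ± 0.09) and Ccnt1 (0.56 ± 0.07) rose too. Of the 32 tested partners 12 rose and 5, namely Mllt3, Kmt2a, Ell2, Aff1 and Dot1l, fell (13 and 5 when adjusted over the list alone, camera adjusted p = 0.0200, and adjusted p = 0.429 with an estimated correlation). Of 61 replication-dependent histone genes, 41 rose and 4, Hist1h1b, Hist1h4f, Hist1h2bk and Hist1h2af, fell (43 and 5 when adjusted over the list alone, camera adjusted p = 1.41e-09, and adjusted p = 0.399 with an estimated correlation). Hist1h4i rose from 255 ± 24.9 to 1167 ± 129 (2.19 ± 0.12), Hist2h2be by 2.41 ± 0.19, Hist1h2an by 1.16 ± 0.07 and Hist1h2bj by 0.80 ± 0.07. Histone genes are near-identical copies, so that reads may be divided among them, and 35.9% of the exon bases of Hist1h2an lie in another gene. Other protein-coding genes with 1 exon had a median of 0.41. The 4 falls were 1 without control replicate 1 or Cdc73-deleted replicate 1 or 2, and 2 without control replicate 3.

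Of 38 Myc targets of ribosome biogenesis 19 rose and 1, Nop58, fell (camera adjusted p = 0.000351, and adjusted p = 0.429 with an estimated correlation), and 4 fell without control replicate 1 and 2 without Cdc73-deleted replicate 3. Odc1 was at 1.03 ± 0.07, Nop56 at 2924 ± 123 and 5844 ± 270 normalized counts in control and Cdc73-deleted cells, Rrs1 at 0.82 ± 0.08 and Mybbp1a at 0.65 ± 0.07. Of 81 cytosolic ribosomal protein genes 21 rose and 6 fell (20 and 5 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.0675). Rps12 was at 1.09 ± 0.10, Rps27a at 1.17 ± 0.19, Rpl12 at 0.72 ± 0.12 and Rpl7l1 at −0.44 ± 0.07. Counts were low for some members, with control means of 87.4 for Rps27a, 280 for Rpl12 and 317 for Rps12. Rpl24 had at most 12.8 normalized counts in any library. Whether reads of ribosomal protein genes were lost because similar copies share them was not tested. Of the list, 9 members rose without Cdc73-deleted replicate 2, 13 rose and 2 fell without Cdc73-deleted replicate 1, and the list was called without Cdc73-deleted replicate 3 (camera adjusted p = 0.0463). Of 29 genes of the integrated stress and unfolded protein responses 14 rose and 6 fell, and the list was not called (camera adjusted p = 0.0550). Ppp1r15a was at 1.25 ± 0.12, Slc3a2 at 0.73 ± 0.07, Xbp1 at −1.20 ± 0.09 and Pdia4 at −0.54 ± 0.06. Of 73 nuclear genes of oxidative phosphorylation 27 fell and 10 rose (29 and 10 when adjusted over the list alone, camera adjusted p = 0.00914, and adjusted p = 0.429 with an estimated correlation). Ndufa2 was at −0.74 ± 0.09, Ndufs7 at −0.66 ± 0.08, Ndufb9 at −0.63 ± 0.08 and Sdha at −0.49 ± 0.07. The rises were 5 without control replicate 1 or Cdc73-deleted replicate 1, and 4 without Cdc73-deleted replicate 2. Of the 7 tested mitochondrially encoded proteins 6 rose (camera adjusted p = 0.0206, and adjusted p = 0.429 with an estimated correlation). The rule for this list also covers genes that were not in the table, so these 7 are a part of the set. mt-Cytb was at 0.45 ± 0.07, mt-Nd4 at 0.43 ± 0.06, mt-Nd1 at 0.33 ± 0.08 and mt-Co1 at 0.22 ± 0.06, and 3 rose without Cdc73-deleted replicate 1. The call of mt-Co1 ended without that library (adjusted p = 0.0553) and without control replicate 2 (adjusted p = 0.0528). Of 21 glycolysis genes 11 rose and 4 fell (camera adjusted p = 0.0357, and adjusted p = 0.429 with an estimated correlation). Hk2 was at 1.09 ± 0.09, Pkm at 0.96 ± 0.09, Hk3 at −1.38 ± 0.11 and Pfkm at −0.79 ± 0.09. This list lost its call without control replicate 1, control replicate 3 or Cdc73-deleted replicate 2 (camera adjusted p = 0.0511, 0.0585 and 0.0564). It also lost it without members of other lists (camera adjusted p = 0.0692). Of 24 cholesterol synthesis genes Pmvk (−0.87 ± 0.20), Nsdhl (−0.87 ± 0.20), Hmgcs1 (−0.35 ± 0.10) and Dhcr7 (−0.36 ± 0.12) fell and Cyp51 and Hmgcr rose, with 3 lower and none higher when adjusted over the list alone. The rises were 3 without control replicate 2 and 0 without any other 1 library, and the falls were 2 without Cdc73-deleted replicate 2. This list was not called (camera adjusted p = 0.296). Dhcr7 was not called without control replicate 1 (adjusted p = 0.0628), nor were Dhcr7 (adjusted p = 0.114) and Hmgcs1 (adjusted p = 0.0611) without Cdc73-deleted replicate 2. Between 10.7% and 19.5% of the exon bases of Gadd45a, Bid, Rps12, Ndufa2, Ndufb9, Pkm, Pfkm and Hmgcs1 lie in exons of another gene. For lists with no separate count, the numbers adjusted over the list alone were those over all genes. In the other splits of the 6 libraries into 3 and 3, camera with the preset correlation called between 6 and 14 lists, against 20 in the real split.

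**Figure D3:**
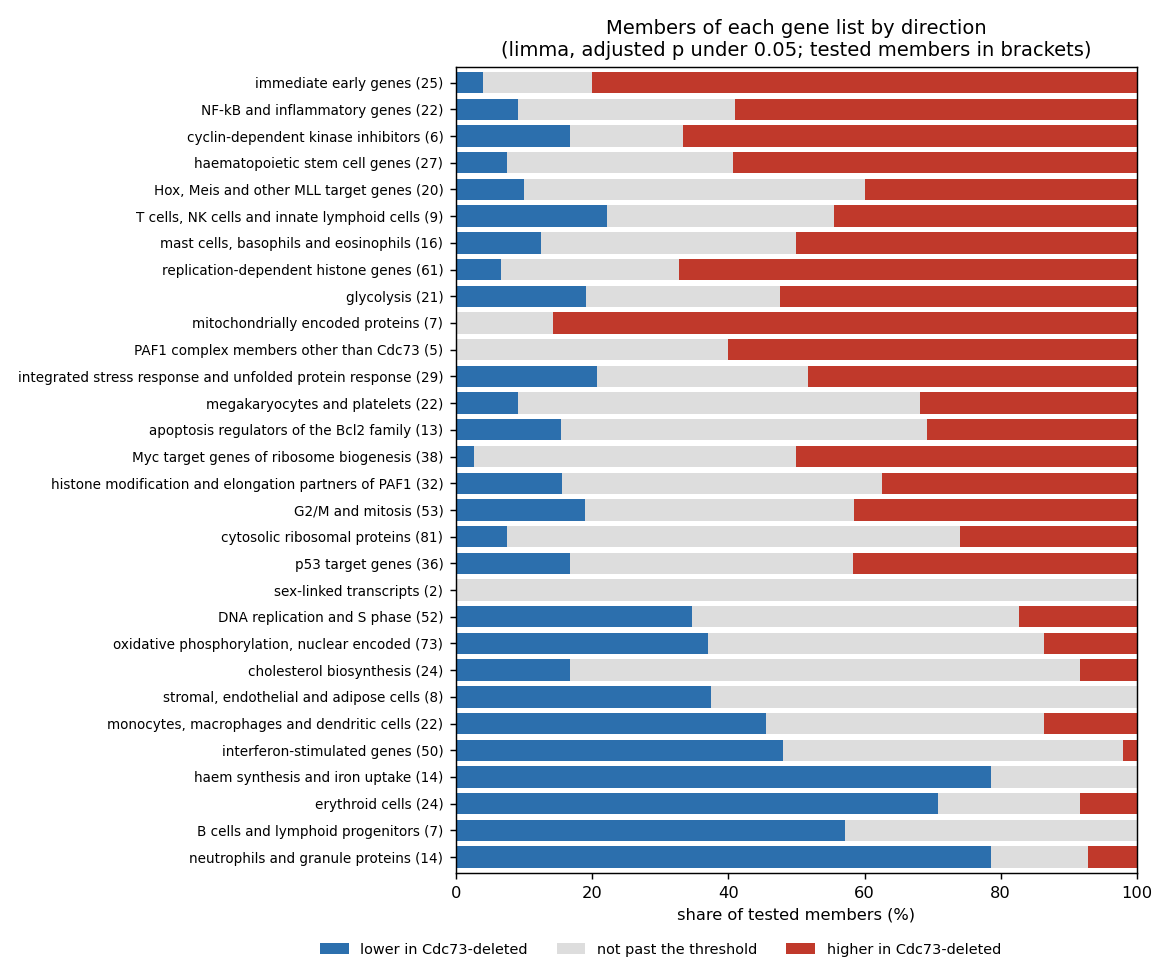
Share of the tested members of each of the 30 gene lists that was lower, higher or not past the threshold in Cdc73-deleted cells (limma, adjusted p under 0.05), ordered by the median change. Haem synthesis genes hold 11 falls among 14 members and immediate early genes 20 rises among 25.

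Mitochondrial transcripts took 9.32% ± 0.36 of reads in control and 9.54% ± 0.66 in Cdc73-deleted libraries (exact permutation p = 0.8). Most of this share came from the ribosomal RNAs mt-Rnr2 and mt-Rnr1, with means of 5.93% and 2.91% of reads over all libraries. It therefore says little about the mitochondrially encoded proteins. Ribosomal protein genes took 1.37% ± 0.05 and 1.34% ± 0.01 (exact permutation p = 0.7), and the 10 most abundant genes took 27.8% ± 0.44 and 28.9% ± 0.94 (exact permutation p = 0.2). The most abundant of these was Gm26917, a gene model similar to ribosomal RNA, with a mean of 12.6% of reads. Gm26917, Gm42418, Gm23935, mt-Rnr1 and mt-Rnr2, which are ribosomal RNA or similar to it and were grouped after the data were seen, took 25.1% ± 0.58 of reads in control and 26.8% ± 1.02 in Cdc73-deleted libraries. This share was higher in all 3 Cdc73-deleted libraries (exact permutation p = 0.1, the smallest possible). The number of genes with at least 1 read was 19412, 20352 and 18078 in the controls and 22004, 22321 and 21160 in the Cdc73-deleted libraries (exact permutation p = 0.1, the smallest possible).

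The authors' deposited table held 17031 rows and gave an adjusted p under 0.05 to 823 genes, 390 of them higher and 433 lower in Cdc73-deleted cells. Of these, 799 were among the genes tested here, and all 799 were called by limma in the same direction. The adjusted p in the authors' deposited table was 1 in 85.2% of rows. Its values were close to those of a DESeq2 test against a null hypothesis of a change up to 1.5-fold on the recovered reads, which called 834 genes and shared 821 with the table, while DESeq2 without that threshold called 6425 genes. With the same 1.5-fold null hypothesis, limma called 932 genes, 442 higher and 490 lower, and 787 of them were in the authors' deposited calls.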

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

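The alternatives chosen after seeing the data were the pseudocounts, TMM and total-count scaling in limma, the block in limma and the 1.5-fold null hypothesis. The others were planned. EdgeR with TMM was planned as the main test, and was run instead as an alternative with the limma filter. Limma became the main test once the deposited values were seen to be normalized. The number of changed genes was between 5251 and 6635 when 1 library was left out and between 5444 and 6986 under the settings that changed the test, scaling, pseudocount, filter or block, and 0 of the shared calls changed direction. Higher genes made up 42.5% to 50.6% of calls under these settings, and 47.8% in the main test. The 1.5-fold null hypothesis left 932 changed genes, 442 higher and 490 lower, and 860 with a change of at least 2-fold; it asks for a larger change. With a mean of at least 5 CPM, which tests 9505 genes, 700 changed at least 2-fold. The median change of all genes was 0.01, and −0.03 with total-count scaling in limma. It was 0.19 with no filter and 0.18 with DESeq2, which tested 26975 and 19119 genes, and −0.06 with a mean of at least 5 CPM. Cdc73 stayed between −1.32 and −1.45 when 1 library was left out.

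Whether the numbers of the replicates pair the libraries stays open. Correlations of deviations were 0.086, 0.007 and 0.059 for equal numbers, each the highest of its library. They lay under 0.1 and the labels state no pairs, so the main test used none. With the replicate block 6986 genes were called by limma and 6814 by edgeR, against 6707 and 6657 without it, and no list changed its call.

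All 20 list calls ended with an estimated correlation, at an adjusted p of 0.399 (stem cell, kinase inhibitor, NF-kB, immediate early, histone, haem, neutrophil, monocyte, B cell and mast cell lists), 0.429 (PAF1, elongation partner, Hox, ribosome biogenesis, mitochondrially encoded, oxidative phosphorylation, glycolysis and erythroid lists), 0.469 (interferon) and 0.550 (G2/M); this setting lets members vary together. By fry, which does not compare a list with other genes, calls ended for G2/M (0.0633) and interferon genes (0.112) and were gained for p53 (0.00191), S phase (0.0344), Bcl2 (0.00226), stress response (0.000776), ribosomal protein (0.00975) and T and NK cell genes (0.00191). The cause was not tested for the following changes. Without members of other lists, calls ended for kinase inhibitors (0.0726) and glycolysis (0.0692). Without a filter, S phase (0.0238) and stress response genes (0.0437) were called; with a mean of 5 CPM the Hox (0.0967) and B cell lists (0.0618) lost and ribosomal proteins (0.0462) gained a call. With total counts only, the PAF1 list had 0.0503 in limma and 0.0506 in edgeR.

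Over the fits without 1 library, adjusted p was between 0.0125 and 0.0636 for PAF1, 0.00870 and 0.0568 for Hox, 0.00363 and 0.0883 for G2/M, 0.0199 and 0.0585 for glycolysis, 0.0140 and 0.0550 for B cell, 0.00923 and 0.0568 for mast cell, 0.0412 and 0.222 for megakaryocyte and 0.0463 and 0.147 for ribosomal protein genes. Among 122 other named genes, over the settings that tested them, 0 calls reversed, 55 were lost, 49 of them under the 1.5-fold null hypothesis, and 1 was gained (Xist with total-count scaling in limma). The 6 others were mt-Co1 and Dhcr7 (2 each), Ctr9 and Hmgcs1, each without 1 library. Most named genes were picked for a large change or small adjusted p in the main test, so these numbers say little about other calls. Over all genes, 77.5% of the main calls were kept without Cdc73-deleted replicate 2, the lowest share among the fits without 1 library. DESeq2 shared 821 of the authors' 823 calls. The number of reads limits what could be tested: 13887 of 26975 genes passed the filter. DESeq2 and the 1.5-fold null hypothesis gave no list test, and sex as a covariate was not run.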

Other observations

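The tests on genomic DNA, on neighbouring protein-coding genes and on histone copies were chosen before their results were seen; the other tests in this part, and all patterns, were chosen after.

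Of 14 neutrophil and granule genes 11 fell and 1 rose, among them Elane at −4.69, Mpo at −2.81, Ctsg at −2.22 and Prtn3 at −2.05 on the log2 scale, and of 22 monocyte, macrophage and dendritic cell genes 10 fell, 3 rose and 9 did not pass the test. If only granulocyte-monocyte progenitors had been lost, the share of every other cell type would have risen alike. The mean change of the stem cell list exceeded that of the erythroid list by 1.295 (95% bootstrap interval over genes 0.771 to 1.78, and 1.86, 1.30 and 0.731 in the 3 libraries). This gap was chosen after both directions had been seen, so it restates them and is not a separate test. Its interval is over genes and does not measure the spread between mice. The fall of the erythroid list beside the rise of the stem cell list argues against that loss as the only change. An even loss of the cells that alone hold the primary granule transcripts would lower these by 1 factor. Their changes differed by up to 2.637 ± 0.168, which argues against an even loss as the only change. This gap is that of the pair furthest apart among 4 transcripts, seen beforehand, and its error treats them as independent. It does not bear on a loss that took some of these cells more than others. Changes in several cell types at once, remaining cells that hold some of these transcripts, and regulation within cells by Cdc73 stay open, since bulk libraries do not give cell numbers.

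Gene models that the annotation lists as to be experimentally checked, called TEC, rose more often than they fell: of 545 tested, 188 rose and 4 fell, with a median of 0.93 (camera adjusted p = 3.40e-09, and adjusted p = 0.0241 with an estimated correlation). Reads from genomic DNA would fall on silent genes too, but smell and pheromone receptor genes went from 0.0339 to 0.0597 normalized counts per kb (exact permutation p = 0.1, the smallest possible), a gain of 0.7548% of that of the TEC models, whose sums were 18.5 ± 1.40 and 21.9 ± 2.96 per kb (exact permutation p = 0.2); receptor copies that share reads would lower their counts. The table held 145 of 1464 annotated receptor genes and 1616 of 3219 TEC models, and absent genes counted as 0, since it held 0 genes without a read; over the genes in the table alone, a check chosen after the result, the gain was 3.39% of that of the TEC models. Protein-coding genes of like expression had medians between 0.0149 and 0.251 in 95% of draws against 0.9315 for the TEC models, which argues against low expression as the cause, and the 32 TEC models more than 5 kb from any protein-coding gene had a median of 0.7928 (95% bootstrap interval 0.480 to 1.01), with 12 higher and 0 lower, which argues against reads of a neighbour as the whole cause. The share of reads from ribosomal RNA and similar genes (25.1% and 26.8%) and the number of genes with a read (18078 to 20352 and 21160 to 22321) were also higher in all 3 Cdc73-deleted libraries; a difference in library composition, unspliced or extended transcripts, less decay and a change of the cell mixture were not tested and stay open, as does a role of Cdc73.

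Of 61 replication-dependent histone genes 41 rose, 4 fell and 16 did not pass the test, with a mean of 0.59 (95% bootstrap interval 0.42 to 0.77, camera adjusted p = 1.41e-09, and adjusted p = 0.399 with an estimated correlation). Whether more cells were in S phase stays open: the DNA replication genes had a mean change of −0.093 (SD over genes 0.33), but 9 rose, such as Pcna and Slbp, and 18 fell, so this mean does not decide it. Reads moved between near-identical copies would leave the sum as it was, but it was 1.351-fold higher, at 196000 ± 7108 and 264700 ± 6870 normalized counts (exact permutation p = 0.1, the smallest possible). Of 212 other protein-coding genes with 1 exon 84 rose and 11 fell (camera adjusted p = 1.57e-06, and adjusted p = 0.0978 with an estimated correlation). The histone median of 0.4122 lay within the 0.277 to 0.485 of draws matched on expression, so it was not set apart from such genes. This does not show a rise of genes without introns in general, since members of the other lists were kept among the 212. The cause of the histone rise, technical or through Cdc73, stays open.

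Other classes of gene models outside proteins had positive medians. It was 0.71 for 280 antisense models, 84 of them higher and 15 lower (camera adjusted p = 6.99e-05, and adjusted p = 0.0445 with an estimated correlation). For 265 lincRNA models it was 0.62, with 88 higher and 15 lower (camera adjusted p = 0.000278, and adjusted p = 0.0685 with an estimated correlation). The largest such class, 640 processed pseudogenes, had a median of 0.15, with 44 higher and 6 lower, and was not called (camera adjusted p = 0.104). The 11606 protein-coding genes had a median of −0.05. Across 11330 protein-coding genes with several exons, the change had a Spearman rho of −0.07 with the length of the gene, and genes are not independent replicates. Of 6 gene families looked at after seeing the data, the intraflagellar transport genes named Ift had 9 lower and 1 higher of 13 (camera adjusted p = 0.00503, and adjusted p = 0.0978 with an estimated correlation), and the 2 tested Id genes rose. The Dusp, Mcm, Slfn and Rgs families were not called (camera adjusted p = 0.129, 0.632, 0.334 and 0.651).

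Igkc, the kappa light chain of antibodies, had 860 normalized counts in control replicate 1 and 896 in Cdc73-deleted replicate 3, and at most 1.59 in each of the other 4 libraries. Jchain had 229 and 178 normalized counts in the same libraries and at most 3.52 in the others, and Epx, of eosinophils, had 147 in control replicate 1 and at most 7.93 in the others. Prg2, also of eosinophils, had 156 normalized counts in control replicate 1, 67.4 in Cdc73-deleted replicate 3 and at most 14.98 in the others.

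The 6 libraries can be split into 3 and 3 in 10 ways, which cannot give a share under 0.05. With limma, the real split gave 6707 changed genes, 3206 higher and 3501 lower and 1847 changed at least 2-fold, and the highest of the other splits was 0 for each. At an unadjusted p under 0.05, the real split gave 7648 genes and the other splits between 38 and 211. Camera called 20 lists in the real split and between 6 and 14 in the other splits, each of which still sets 2 libraries of a group against 1. Splits were counted with limma alone.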
